A study of Oryza sativa with 9 samples.

How the data were processed

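RNA from rice roots (cultivar Tsukinohikari, hydroponic culture) was compared on 9 two-colour Agilent arrays, 3 per treatment. The plants had iron in the solution up to 7 days (+Fe 7d), or had been without it for a single day (-Fe 1d) or for 7 days (-Fe 7d). Each array held RNA of an HRZ2i line, an RNA interference line against OsHRZ2, beside RNA of the non-transformant (NT). Each of the 3 HRZ2i lines gave 1 array per treatment. Line 1 was labelled with Cy3 and lines 2 and 3 with Cy5. The arrays of lines 2 and 3 carried the same NT replicate at +Fe 7d and at -Fe 1d, so 7 NT extracts stood behind the 9 arrays.

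Per the file headers, the scanner files hold the mean intensity of each spot and its local background in both channels, read with Agilent Feature Extraction 10.5.1.1. The same files also hold intensity values that the software had background-subtracted and dye-normalised, and per the file headers their log10 ratio of Cy5 over Cy3. The deposited value table holds that log10 ratio turned to HRZ2i over NT, which was checked on every spot of each array (largest gap 4.99e-06). Median spot signals ran from 657 to 903 in Cy3 over a background of 27 to 30, and from 1044 to 1562 in Cy5 over a background of 62 to 64. Between 79.6% and 82.9% of the probes were well above background in a channel, and 0 probes were saturated. For arrays, the number of arrays limits the precision.

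All analysis started from the mean intensity of the scanner files, which the authors had not normalised, in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Both channels were background-corrected by normexp with an offset of 50, and the log2 ratio was normalised by loess within each array. The 2007 control spots of the 45151 spots per array took no weight. Spots marked as outliers by the scanner software, 9 to 28 per array, were set as missing, and repeated spots of a probe were averaged. From 42418 probes, those well above background in at least 1 channel on 3 of the 9 arrays were kept, and the brightest probe stood for each locus. This left 24986 genes. Of these, 927 shared their probe sequence with another tested gene, so that 24263 distinct sequences were tested and genes of a shared sequence cannot be told apart.

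The log2 ratio of HRZ2i over NT was fitted with limma on all 9 arrays. The fit held a coefficient per treatment, a common dye term, and the NT extract as a random block with a consensus correlation of 0.623. Since line 1 alone had its dyes the other way round, at every treatment, the dye term cannot be told apart from a difference between line 1 and lines 2 and 3, and it takes such a difference out of the residual spread. The fit had 5 residual degrees of freedom and 2.2 prior degrees of freedom. Differences between treatments were contrasts in that fit. The NT response to iron deficiency used the NT channel after quantile normalisation of average intensities between arrays. Arrays of an extract were averaged first, and 7 extracts with a dye term left 3 residual degrees of freedom. All tests were two-sided with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p below 0.05. Folds are given as at least N-fold where an arm was not well above background on any array of the treatment, from the mean levels of both arms, and left out where that exceeds the fitted fold. Gene lists, 26 in all, were tested with the camera test of limma on the moderated t with a preset correlation of 0.01, and again with an estimated correlation, with fry and with ranks. Counts of list members are given over all genes and adjusted over the list alone.

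The tests of the comparisons, the lists, the rule for the genes named and the other settings were chosen before the data were examined, except for a fit on lines 2 and 3 alone, the list test with the line as replicate block, and tests that the text gives as chosen later. The rule took HRZ1 and HRZ2, the members of 6 lists fixed by locus, and the 10 largest called changes each way with the same sign on all 3 arrays and a gene description. For differences and NT responses it took the 5 largest each way and called list members, and for lists fixed by words in descriptions up to 4 called members. A description that names nothing was not counted as one, so 15299 genes could enter by it, and that reading was set after the data were seen. List members whose array description contradicted their symbol were left out, namely NRAMP5, ENA2, bHLH133, bHLH156 and HORZ1. YSL18, IMA2, ZIP3 and ZIP10 did not pass the filter. HRZ1 was read from locus Os01g0689300, the only other locus on the array described as an HHE domain protein, next to the locus fixed for it, and NAAT1 from a neighbouring locus number whose description names it. These loci were assigned after the data were seen.

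The line numbers pair the samples across treatments. The deviations of arrays of a line from their treatment mean correlated across genes (r from 0.277 to 0.670 over 9 pairs). By these deviations 9 of 9 arrays were closest to their own line, but deviations from a shared mean push other lines apart. By the ratios themselves, line 2 was closest to line 3 at +Fe 7d (r = 0.706, own line at most 0.622). The same held at -Fe 1d (r = 0.6955, own line at most 0.652). The arrays of line 1 also share their reversed dyes. A replicate block, with the line as a fixed term in place of the dye term, was among the settings chosen beforehand. It takes all differences between the lines out of the residual spread. For HRZ2i against NT its p-values and counts therefore do not measure whether an effect repeats over the lines. The further settings were no dye term, arrays as independent, an offset of 16, no background correction, the software's processed intensity, the deposited log10 ratios, median centring, scale normalisation between arrays, no filter and a strict filter, all probes, a trended robust fit, only the arrays of a comparison without the dye term, a 2-fold limit and leaving out each replicate. The NT responses had quantile normalisation, no dye term, no filter and their own replicate block, on NT replicates 1 and 2. The consensus correlation was kept at 0.623 for leaving out arrays, for the arrays of a comparison, for the trended fit and for other splits.

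The steps were tested on simulated data. These held no differences between lines, and the largest spreads of genes were cut down. The shares below therefore need not hold for the real arrays, where arrays of a line deviate alike. At +Fe 7d, the fit on 24986 genes recovered 79.1% of 67 genes changed 2-fold, 98.5% of 67 changed 4-fold and 100% of 66 changed 8-fold, and 5.61% of its calls were unchanged genes. For the difference of -Fe 7d minus +Fe 7d the shares on 24986 genes were 58.2%, 88.1% and 97.0%. For the NT response at -Fe 7d they were 29.9%, 86.6% and 93.9%, with 6.04% of calls unchanged. With nothing changed at -Fe 1d, 0 genes were called by limma and 4.92% had an unadjusted p below 0.05.

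Each treatment lay on its own slide, so slide and treatment cannot be told apart in differences between treatments or in the NT responses, and -Fe 1d differs from +Fe 7d in day as well. Nothing in the labels says that samples came from separate cultures, so the p-values measure the spread between these samples. No genome was at hand and no coordinates are given. Loci are named as on the array. Their numbers were used only to tell the chromosome and, by their order, which genes neighbour each other.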

Results

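Root transcripts of 3 HRZ2i lines were set against those of NT on 9 two-colour arrays, 1 array per line and treatment (n = 3 arrays per treatment). HRZ2 is a ubiquitin ligase with hemerythrin domains that acts against the iron deficiency response in rice, and the comparison asks what its knockdown does to root transcripts with and without iron. Values are log2 ratios of HRZ2i over NT, with the standard error of the limma fit, and 24986 genes were tested. That standard error leaves out the difference between line 1 and lines 2 and 3, which the dye term takes up. Fitted values are not plain means over the lines, since with the dye term line 1 counts for more than line 2 or line 3. The arrays carried 2 or 3 NT extracts per treatment and had 42418 probes each, of which at least 79.6% were well above background in either channel.

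The target itself, HRZ2 (Os05g0551000), was lower in HRZ2i on all 9 arrays by the probe used. At +Fe 7d the log2 ratios of lines 1, 2 and 3 were -0.73, -0.45 and -0.80, at -Fe 1d they were -0.48, -0.48 and -0.80, and at -Fe 7d they were -0.96, -0.55 and -1.22. The fitted log2 ratio was -0.67 ± 0.19 at +Fe 7d and -0.57 ± 0.19 at -Fe 1d, neither past the threshold (limma adjusted p = 0.142 and 0.143). At -Fe 7d it was -0.91 ± 0.17 and passed (limma adjusted p = 0.0417). With the line as replicate block the adjusted p of limma was 0.00631 at +Fe 7d and 0.0130 at -Fe 1d. That fit leaves the differences between lines out of the spread, so these values do not test whether the fall repeats over lines. The call at -Fe 7d ended without the array of line 1 (limma adjusted p = 0.430) or of line 3 (0.130). A dimmer probe of HRZ2 gave log2 ratios of the other sign, 1.19, 0.99 and 1.13 in the order of the treatments, none of them called (limma adjusted p = 0.103, 0.117 and 0.0905). The position of the RNA interference trigger is not given in the sources used here. HRZ1, the paralog of HRZ2 and read from locus Os01g0689300, had log2 ratios of -0.06 at +Fe 7d and -0.07 at -Fe 1d, and fell by 0.56 ± 0.07 at -Fe 7d (limma adjusted p = 0.772, 0.614 and 0.00651). That call of HRZ1 ended without the array of line 1 (limma adjusted p = 0.169).

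With iron in the solution, HRZ2i roots had far more transcripts for mugineic acid synthesis and iron uptake than NT roots. All 10 genes of this list were higher at +Fe 7d, 10 adjusted over the list alone, with a median log2 ratio of 2.67. The nicotianamine synthases NAS1 (Os03g0307300) and NAS2 (Os03g0307200), which make the precursor of mugineic acids, rose by 5.61 ± 0.42 and 5.39 ± 0.53, or 48.9-fold and 41.8-fold (limma adjusted p = 0.000705 and 0.00270, n = 3 arrays). YSL15 (Os02g0650300), which takes up the ferric mugineic acid complex, rose by 3.79 ± 0.54. The mugineic acid exporter TOM1 (Os11g0134900) rose by 2.66 ± 0.21 and the ferrous iron transporter IRT1 (Os03g0667500) by 1.27 ± 0.25 (limma adjusted p = 0.000905 and 0.0457), where another probe of IRT1 gave 1.26 and was not called (limma adjusted p = 0.0571). DMAS1, NAAT1, NRAMP1, ENA1 and IRT2 lay between, from 2.10 to 2.90. The camera test put the list above other genes (adjusted p = 1.58e-33, and adjusted p = 0.0412 with an estimated correlation). NAS1 and NAS2 are close paralogs, and cross-hybridisation between them cannot be excluded.

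The methionine cycle, which supplies the substrate of nicotianamine synthase, rose along with it at +Fe 7d. Of its 12 genes 9 were higher, 9 adjusted over the list alone, with a median log2 ratio of 0.91 (camera adjusted p = 5.66e-24, and adjusted p = 0.0159 with an estimated correlation). DEP (Os11g0484000) rose by 2.26 ± 0.15, IDI4 by 2.07 ± 0.19, ARD2 by 1.53 ± 0.14 and MTN by 1.18 ± 0.09 (limma adjusted p = 0.000350 for DEP). ARD1, FDH1 and SAMS1 were not called, with log2 ratios of 0.61, 0.38 and 0.32.

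Among 8 genes of iron translocation, 2 were higher at +Fe 7d, 5 adjusted over the list alone. They were the nicotianamine synthase NAS3 (Os07g0689600), with 1.70 ± 0.24, and MIR (Os12g0282000), a gene known to respond to iron deficiency, with 1.31 ± 0.15 (limma adjusted p = 0.0142 and 0.00581). The list median was 0.99 (camera adjusted p = 5.60e-05, but adjusted p = 0.0642 with an estimated correlation). Iron storage went the other way. The ferritins FER2 (Os12g0106000) and FER1 (Os11g0106700), which store iron in plastids, fell by 1.04 ± 0.10 and 0.84 ± 0.10 (limma adjusted p = 0.00195 and 0.00666). These were 2 lower of 4 genes, 2 adjusted over the list alone, and the vacuolar iron transporters VIT2 and VIT1 had log2 ratios of -0.43 and -0.04 (camera adjusted p = 5.60e-05, but adjusted p = 0.0848 with an estimated correlation). Of 8 iron regulators 1 was higher, 2 adjusted over the list alone. This was the peptide gene IMA1 (Os01g0647200), with 1.28 ± 0.24 (limma adjusted p = 0.0370) by the probe used and 1.23 by another, but 2 further probes of the locus gave 0.12 and 0.06 and were not called (limma adjusted p = 0.766 and 0.903). The transcription factors IRO2 and IRO3 had uncalled log2 ratios of 1.97 ± 0.52 and 1.49 ± 0.51. The regulator list was not called (median 0.08, mean 0.58, camera adjusted p = 0.236, but adjusted p = 0.00411 with the line as replicate block), nor was zinc and other metal transport with 0 of 9 genes called by limma, 0 adjusted over the list alone (camera adjusted p = 0.99). Germin-like genes were lower as a list at +Fe 7d, with 5 of 22 genes called lower, 5 adjusted over the list alone, and a median of -0.14 (camera adjusted p = 0.0107, but adjusted p = 0.690 with an estimated correlation). The largest falls were in Os08g0189500 and Os08g0189600, by 2.68 ± 0.44 and 2.35 ± 0.22 (limma adjusted p = 0.0249 and 0.00217).

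**Figure D1:**
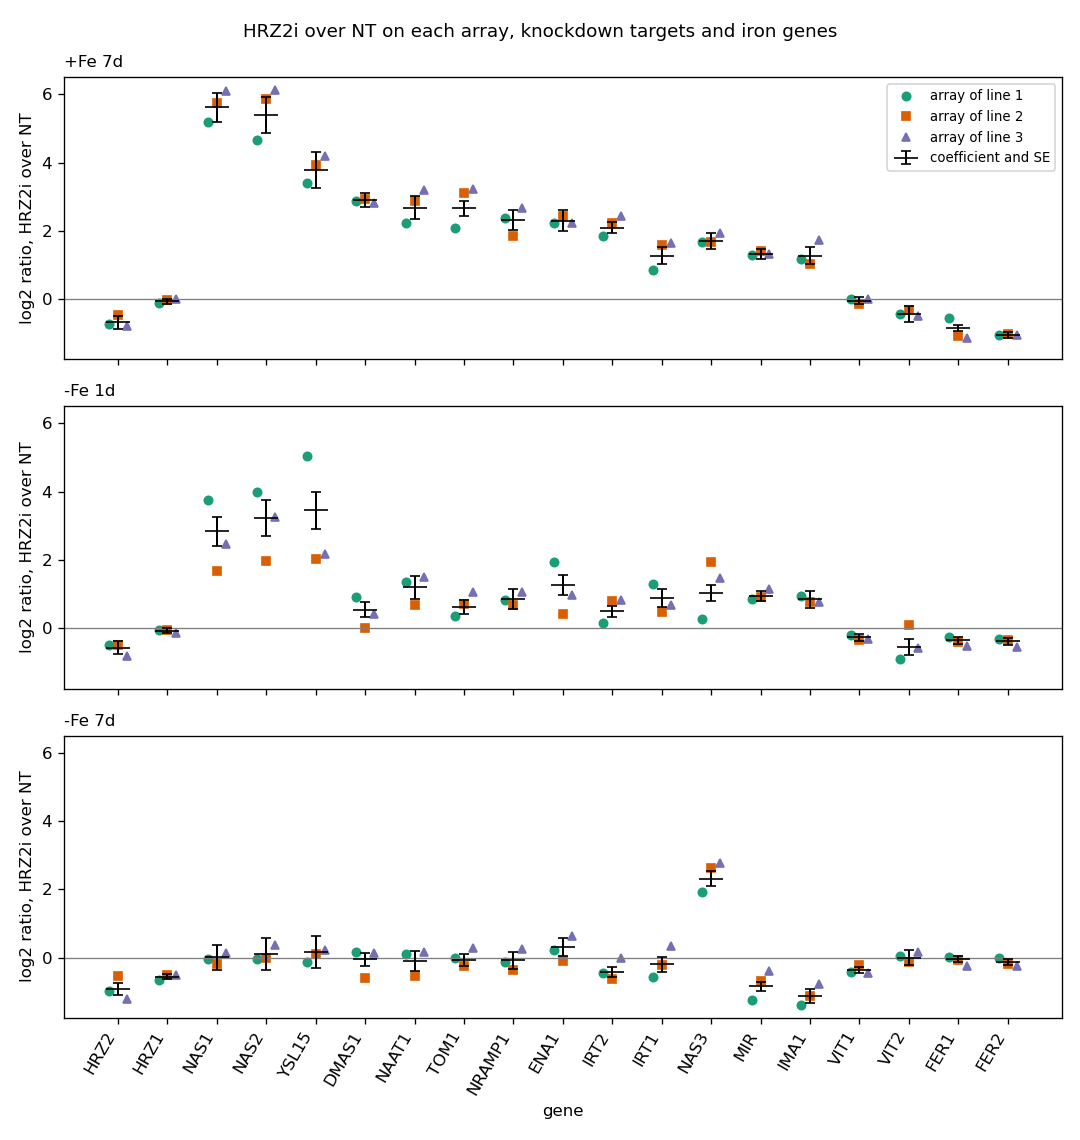
Log2 ratio of HRZ2i over NT (vertical axis, log2 units) of named iron genes (horizontal axis) in 1 panel per treatment, with 1 point per array for lines 1 to 3 and a bar for the limma coefficient ± its standard error. NAS1 lies at 5.61 with iron, 2.84 after 1 day without it and 0.01 after 7 days, while NAS3 lies at 1.70, 1.03 and 2.31.

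Over all genes at +Fe 7d, 434 were higher and 330 lower, 235 and 84 of them at least 2-fold. The 764 called genes stand for 641 distinct probe sequences, and 753 had the same sign on all 3 arrays. Among called genes with a description, the largest ratio was that of Os11g0639600, a disease resistance protein, with 6.92 ± 0.16 or 121-fold by the probe used and 4.55 by its other probe. The transposon-like Os06g0271500 was at least 46.6-fold higher by the probe used and had 4.06 by its other probe, and the glycosyltransferase Os09g0329700 had 4.90 ± 0.09. Os12g0132500, an antiporter of the major facilitator family, rose by 3.28 ± 0.23. The SPX domain protein Os02g0202200 had -4.12 ± 0.33, and the oxygenase Os09g0353700 -3.17 ± 0.22. The limma adjusted p of these genes ran from 1.04e-06 to 0.000923.

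The counts at +Fe 7d fell without line 1 and moved with how the lines were modelled. Without line 1, the arrays left at +Fe 7d have the same dye orientation and the same NT replicate. The dye term then comes from the other treatments, so lost calls and moved ratios mix this layout with any dependence on line 1. Without the array of line 1, whose dyes are the other way round, limma called 100 genes higher and 26 lower. The uptake genes called were then 5 of 10 and the methionine genes 4 of 9, while YSL15, IRT1, ARD2, NAS3, MIR, IMA1 and FER2 were not called (limma adjusted p = 0.0898, 0.221, 0.0785, 0.253, 0.163, 0.340 and 0.0875) and germin-like Os08g0189500 and Os08g0189600 neither (0.340 and 0.0893). Their log2 ratios were then 4.63 for YSL15 beside 3.79, 1.62 for IRT1, 1.55 for ARD2, 1.27 for NAS3, 1.14 for MIR, 1.31 for IMA1, -0.96 for FER2, -2.36 for Os08g0189500 and -2.21 for Os08g0189600. Without line 2 or line 3 the lower genes were 197 and 164, and IRT1 was not called (limma adjusted p = 0.101 and 0.108), nor was Os08g0189500 without line 2 (0.0622). With the line as replicate block the counts were 1106 and 1175.

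After 1 day without iron, genes of mugineic acid synthesis and uptake were higher in HRZ2i too. YSL15 had 3.46 ± 0.54, NAS2 3.22 ± 0.53 and NAS1 2.84 ± 0.42 (limma adjusted p = 0.0257, 0.0309 and 0.0215, n = 3 arrays). Line 1 gave the highest value of each, for NAS1 3.76 beside 1.68 and 2.46. These were 3 of the 10 uptake genes, 10 adjusted over the list alone, with a median log2 ratio of 1.05 (camera adjusted p = 9.03e-06, but adjusted p = 0.784 with an estimated correlation). MIR rose by 0.94 ± 0.15 (limma adjusted p = 0.0269), the only call of 8 translocation genes, 2 adjusted over the list alone (median 0.77, camera adjusted p = 0.0294, but adjusted p = 0.784 with an estimated correlation). Of the methionine cycle 0 genes were called by limma, 0 adjusted over the list alone, at a median of 0.15, and 0 of the regulators, 2 adjusted over the list alone. Of the storage genes 0 were called, 3 lower adjusted over the list alone, with FER2 at -0.38 and FER1 at -0.35.

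Other lists with a camera call at -Fe 1d held few called genes. Histone genes had a median of -0.18, with 1 of 63 called lower, 1 adjusted over the list alone, a histone deacetylase (Os11g0200000, -0.75 ± 0.12). Their camera adjusted p was 0.00915, but adjusted p = 0.854 with an estimated correlation. Jasmonate genes had a median of 0.15 (camera adjusted p = 0.00547, but adjusted p = 0.854 with an estimated correlation). Their call among 32 genes, 1 adjusted over the list alone, was the ZIM domain gene Os07g0153000, with log2 ratios of 1.45, 5.62 and 5.44 in lines 1 to 3, whose probe sequence is shared with another locus. The dye term takes up that difference of line 1, and without it the gene was not called (limma adjusted p = 0.215).

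Over all genes at -Fe 1d, 381 were higher and 226 lower, 222 and 53 at least 2-fold, standing for 524 distinct probe sequences. Os11g0639600 was higher again, with NT not well above background and so without a fold. The glycine-rich protein Os07g0511100 had 5.93 ± 0.22, and Os02g0202200 fell by 3.88 ± 0.33 (limma adjusted p = 2.68e-06, 2.10e-05 and 0.00157). Without the array of line 1 the counts were 90 and 17, and NAS1, NAS2 and MIR were not called (log2 ratios 1.90, 2.25 and 0.82, limma adjusted p = 0.429, 0.606 and 0.551), nor was Os02g0202200 (-3.31, 0.0554). The arrays left at -Fe 1d in that fit again had the same dye orientation and the same NT replicate. Without line 2 the counts were 248 and 149. Without line 3, YSL15, NAS1, NAS2 and MIR were not called (limma adjusted p = 0.0532, 0.0507, 0.0552 and 0.0553). With the line as replicate block they were 1235 and 1217.

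After 7 days without iron, the log2 ratios of the uptake and methionine genes lay near 0. By limma 0 of the 10 uptake genes were called, 0 adjusted over the list alone, and their log2 ratios ran from -0.43 (IRT2) to 0.31 (ENA1) around a median of -0.06, with NAS1 at 0.01 ± 0.37. Of the methionine genes 0 were called, 0 adjusted over the list alone, at a median of -0.21. NAS3 rose by 2.31 ± 0.21 (limma adjusted p = 0.00181), and MIR and IMA1, higher at +Fe 7d, fell by 0.84 ± 0.13 and 1.12 ± 0.21 (limma adjusted p = 0.0219 and 0.0392, n = 3 arrays). Among 8 translocation genes 1 was higher and 1 lower, as adjusted over the list alone. Of the storage genes 0 were called by limma, 1 lower adjusted over the list alone (VIT1, -0.36).

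Photosynthesis genes, listed as markers of shoot tissue, were lower as a list at -Fe 7d, with a median of -0.32 (camera adjusted p = 0.0147, but adjusted p = 0.884 with an estimated correlation). Of 45 genes 1 was higher and 1 lower, the same adjusted over the list alone, the photosystem subunit PsbS (Os01g0869800, 1.04 ± 0.14) and a chlorophyll-binding protein (Os11g0242800, -0.42 ± 0.08). Jasmonate genes had a median of 0.11, with 0.23 and 0.69 in lines 1 and 2 but -0.41 in line 3 (camera adjusted p = 0.0147, but adjusted p = 0.884 with an estimated correlation), with Os07g0153000 as the call, 1 adjusted over the list alone, which ended without the dye term (limma adjusted p = 0.141). Histone genes had a median of -0.08, with -0.18, -0.11 and 0.05 in lines 1 to 3, and 1 lower of 63, 1 higher and 11 lower adjusted over the list alone (camera adjusted p = 0.0354, but adjusted p = 0.884 with an estimated correlation and 0.173 with the line as replicate block). Their call was histone H2A (Os03g0279200, -0.63 ± 0.12).

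Over all genes at -Fe 7d, 404 were higher and 286 lower, 209 and 54 at least 2-fold, standing for 564 distinct probe sequences. Os11g0639600 was at least 132-fold higher by the probe used and had 4.60 by its other probe, Os09g0329700 had 5.53 ± 0.08, and Os02g0202200 fell by 4.42 ± 0.29 (limma adjusted p = 9.83e-07, 2.47e-07 and 0.000301). Without the arrays of lines 1, 2 and 3 in turn the higher genes were 140, 212 and 247 and the lower genes 37, 116 and 84. IMA1 was then not called (limma adjusted p = 0.458, 0.128 and 0.0794), nor MIR without line 1 or 2 (0.326 and 0.0866) or NAS3 without line 1 (0.0504). With the line as replicate block the counts were 765 and 785.

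Ribosomal protein genes had medians slightly below 0 at all 3 treatments, -0.13 at +Fe 7d, -0.19 at -Fe 1d and -0.15 at -Fe 7d over 298 genes. The camera test called the list each time (adjusted p = 9.07e-05, 3.51e-07 and 4.71e-07), but adjusted p = 0.741, 0.854 and 0.884 with an estimated correlation. At +Fe 7d 1 gene was called, higher (Os04g0247700, 0.53 ± 0.09), at -Fe 1d 1 lower (Os02g0489400, -0.48 ± 0.09) and at -Fe 7d 1 lower (Os05g0459900, -0.77 ± 0.10). Adjusted over the list alone the calls were 0, 0 and 1.

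Many genes had a large ratio at every treatment. The effects correlated across genes, which are not independent replicates, with r = 0.697 for +Fe 7d and -Fe 1d, 0.798 for +Fe 7d and -Fe 7d, and 0.787 for -Fe 1d and -Fe 7d (rho = 0.495, 0.624 and 0.629). At all 3 treatments 190 genes were called higher and 69 lower. Between +Fe 7d and -Fe 7d 295 higher and 139 lower calls were shared. Independent lists of these sizes would share 7.02 and 3.78, but the same 3 lines stand in both treatments, so that is not the chance value for them. Called in opposite directions were 5 genes, named after their values were seen: MIR, IMA1 by the probe used (2 of its 4 probes showed no rise at +Fe 7d), Os01g0871600 (1.81 and -0.96), Os03g0439700 (1.11 and -0.70) and Os08g0414200 (0.45 and -0.76).

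**Figure D2:**
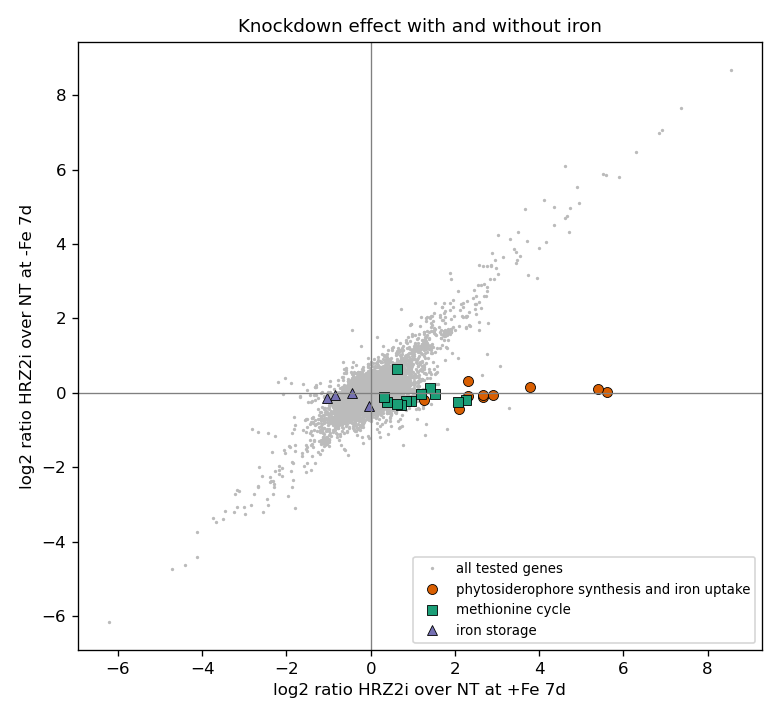
Log2 ratio of HRZ2i over NT at -Fe 7d (vertical axis) against that at +Fe 7d (horizontal axis), with 1 point per gene for all 24986 genes and the uptake, methionine and storage lists in colour. The uptake genes lie at 1.27 to 5.61 on the horizontal axis and at -0.43 to 0.31 on the vertical axis, off the diagonal on which most genes with large ratios lie.

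The difference between treatments was tested directly. From +Fe 7d to -Fe 7d the log2 ratio fell for 12 genes and rose for 1. It changed by -5.60 ± 0.55 for NAS1, -2.95 ± 0.28 for DMAS1, -2.73 ± 0.28 for TOM1 and -2.52 ± 0.21 for IRT2. In the methionine cycle the change was -2.46 ± 0.19 for DEP and -1.23 ± 0.12 for MTN, and outside the lists -3.69 ± 0.30 for the antiporter Os12g0132500. The limma adjusted p of these ran from 0.0287 to 0.0382. The gene called the other way was the peroxidase Os01g0962900, with 1.18 ± 0.11 (limma adjusted p = 0.0378). The uptake list had 4 lower genes, 10 adjusted over the list alone, and a median difference of -2.75 (camera adjusted p = 3.27e-101, and adjusted p = 0.00316 with an estimated correlation). The methionine list had 2, 10 adjusted over the list alone, and a median of -1.13 (camera adjusted p = 1.99e-85, and adjusted p = 0.000707 with an estimated correlation). Translocation, with 1 lower and 2 adjusted over the list alone, had a median of -0.47. Storage, with 0 called by limma but 2 higher and 1 lower adjusted over the list alone, had a median of 0.61. The camera calls of both also held with an estimated correlation (adjusted p = 0.0182 and 0.0374). Leaving out any of the 6 arrays left 0 higher genes and 0 lower genes called by limma, except without the array of line 2 at -Fe 7d, where IRT2 remained and the lower count was 1. With the line as replicate block there were 5 higher and 30 lower genes. With a trended robust limma fit 0 genes were called.

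Between +Fe 7d and -Fe 1d, 0 genes were called by limma (2207 at an unadjusted p below 0.05), but 12 were higher and 16 lower with the line as replicate block. The methionine list was lower at -Fe 1d, with 0 genes called, 9 lower adjusted over the list alone, and a median of -0.97 (camera adjusted p = 5.28e-29, and adjusted p = 0.00981 with an estimated correlation). The uptake list had a median of -1.53, 0 genes called and 7 adjusted over the list alone (camera adjusted p = 3.25e-17, but adjusted p = 0.172 with an estimated correlation). Between -Fe 1d and -Fe 7d, 0 genes were called by limma (1365 at an unadjusted p below 0.05). The uptake list had a median difference of -1.02, with 0 called and 6 adjusted over the list alone (camera adjusted p = 5.20e-16, but adjusted p = 0.382 with an estimated correlation). Slide and treatment cannot be told apart in these differences, and +Fe 7d and -Fe 1d differ in day too.

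In NT roots, genes of the same uptake and methionine lists were higher after 7 days without iron. Among 10 uptake genes 8 were higher at -Fe 7d than at +Fe 7d, 10 adjusted over the list alone, at a median of 3.65. NAS1 rose by 5.23 ± 0.71, IRT2 by 4.65 ± 0.26 and DMAS1 by 4.10 ± 0.15 (limma adjusted p = 0.0357, 0.00548 and 0.00262), while NAS2 and YSL15, with 4.69 ± 0.87 and 3.66 ± 0.88, were not called. Of 12 methionine genes 9 were higher, 9 higher and 1 lower adjusted over the list alone, at a median of 1.32. IMA1 rose by 5.52 ± 0.38, IRO2 by 3.61 ± 0.25, OPT7 by 4.03 ± 0.24, MIR by 3.74 ± 0.45 and HRZ1 by 1.69 ± 0.18 (limma adjusted p from 0.00717 to 0.0291). VIT2, FER2 and FER1 fell by 2.62 ± 0.33, 2.38 ± 0.21 and 2.24 ± 0.15, which made 3 lower of 4 storage genes, 3 adjusted over the list alone, at a median of -2.31. HRZ2 had a log2 ratio of 0.57 (limma adjusted p = 0.0846). Class III peroxidases were lower in 11 of 112 genes, 25 lower and 1 higher adjusted over the list alone, among them Os07g0531400 with a fall by 5.33 ± 0.21.

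The camera calls in this NT response all missed the threshold with an estimated correlation. For uptake the adjusted p was 5.65e-61, but adjusted p = 0.0522 with an estimated correlation, and for methionine 2.71e-26 against 0.0599. For translocation, with 3 of 8 higher and 3 adjusted over the list alone, it was 1.03e-07 against 0.0599, for storage 3.91e-11 against 0.0522 and for peroxidases 3.80e-13 against 0.0522. Regulators, with 3 of 8 higher and 3 adjusted over the list alone, had a median of -0.13 but a mean of 1.15, and the test called them up (camera adjusted p = 0.00138, but adjusted p = 0.450 with an estimated correlation). Over all genes 263 were higher and 343 lower. Without an extract in turn the counts were 9 and 3 (+Fe 7d NT 1), 22 and 61 (+Fe 7d NT 2), 11 and 17 (-Fe 7d NT 1), 20 and 39 (-Fe 7d NT 2) and 31 and 45 (-Fe 7d NT 3). Of 37 named genes 28, 23, 25, 18 and 19 were then not called, while IRT2, DMAS1 and OPT7 were called without any of the extracts. The fits without an extract of +Fe 7d left 1 extract there. With the NT replicate number as replicate block, on NT 1 and 2 alone, the counts were 31 and 45. That is the same fit as without -Fe 7d NT 3, since the replicate number equals the dye, so it does not test pairing. In that fit 19 of 37 named genes were not called, with limma adjusted p from 0.0523 to 0.136, among them NAS1, MIR, HRZ1, FER2 and VIT2.

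Already 1 day without iron, NT roots differed from those at +Fe 7d in 5002 higher and 4164 lower genes. These samples differ in day as well as in iron and slide, and without an extract in turn limma called as few as 651 and 596 (without +Fe 7d NT 1), 1569 and 1242 (-Fe 1d NT 1) or 2916 and 2460 (-Fe 1d NT 2). Each of those fits left 1 extract in the treatment concerned. On all extracts FER2 and FER1 fell by 1.82 ± 0.22 and 1.60 ± 0.16, and VIT2 rose by 1.44 ± 0.36 (limma adjusted p = 0.00691, 0.00540 and 0.0293). Of the uptake genes DMAS1 rose by 0.85 ± 0.16 and TOM1 fell by 1.41 ± 0.27 (limma adjusted p = 0.0146 and 0.0154), and the list was not called (camera adjusted p = 0.689). VIT2 was not called without +Fe 7d NT 1 or 2 or -Fe 1d NT 1 or 2 (limma adjusted p = 0.193, 0.0620, 0.0566 and 0.141), DMAS1 without +Fe 7d NT 1 or 2 or -Fe 1d NT 2 (0.0861, 0.0593 and 0.0549), and TOM1 without +Fe 7d NT 1 or -Fe 1d NT 1 (0.0580 and 0.0905). Ribosomal protein genes were higher in 203 and lower in 6 of 298 genes at a median of 0.71, and 217 higher and 12 lower adjusted over the list alone (camera adjusted p = 8.20e-16, but adjusted p = 0.853 with an estimated correlation). In the same comparison photosynthesis genes, listed as markers of shoot tissue, had 2 higher and 17 lower of 45, 2 and 20 adjusted over the list alone (camera adjusted p = 4.72e-05, but adjusted p = 0.853 with an estimated correlation).

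The knockdown effect with iron was set against the NT response to 7 days without it. Both hold the NT extracts of +Fe 7d, so chance alone makes them correlate. Across genes r was 0.130 and rho 0.0673, and simulated data without effects gave an r of 0.57 through the shared extracts. The covariance of 0.0272 was close to the 0.0286 of those simulations. With disjoint extracts r was 0.0560 and 0.116, and rho -0.0306 and 0.0268. The covariance was then 0.0132 and 0.0249, so a positive covariance remained where no extract was shared. Of 434 genes higher in HRZ2i 40 were also higher in iron-deficient NT, and of 330 lower genes 25 were also lower. Independent lists would share 4.57 and 4.53. Simulations without effects give no fair chance value for these counts. At the threshold used they called 0 genes in either comparison by limma and so shared 0. In 20 simulations added after the data were seen, lists forced to the observed sizes shared 72 to 102 higher and 88 to 110 lower genes, more than observed. Part of the overlap may come from the shared extracts, and how much was not settled. Against the NT response at -Fe 1d, 50 higher and 116 lower genes were shared, where independent lists would share 86.9 and 55. Of the 40, 19 belonged to the lists fixed by locus and 21 did not, among them Os12g0132500 (3.28 in HRZ2i, 4.31 in NT), the cytochrome P450 Os10g0440000 (3.07 and 3.44) and the copper ATPase Os04g0556000 (0.67 and 1.24), named after their values were seen. Of the 25, 2 were FER1 and FER2.

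**Figure D3:**
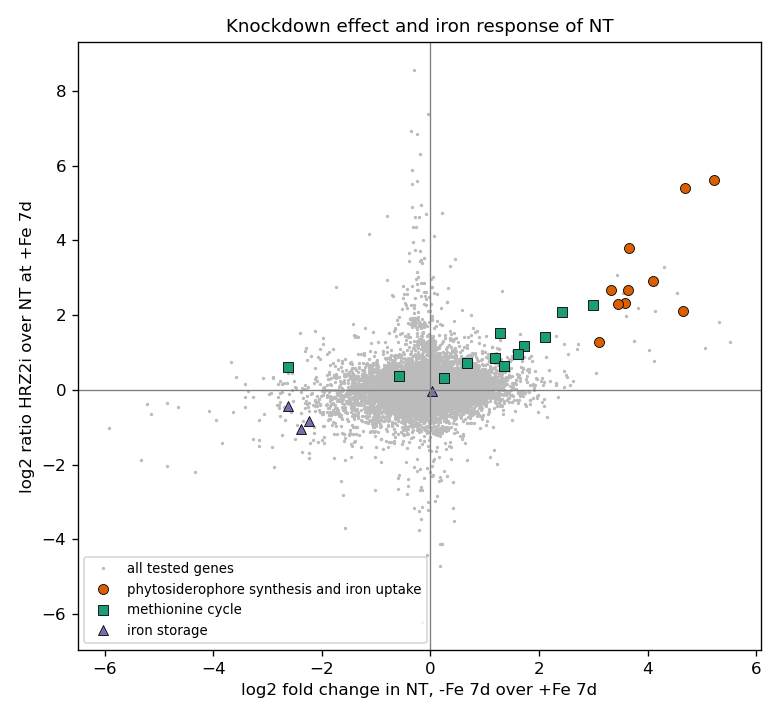
Log2 ratio of HRZ2i over NT at +Fe 7d (vertical axis) against the log2 ratio of NT at -Fe 7d over NT at +Fe 7d (horizontal axis), with 1 point per gene and the uptake, methionine and storage lists in colour. NAS1 lies at 5.23 on the horizontal and 5.61 on the vertical axis, and FER2 at -2.38 and -1.04, while most genes with large values lie along an axis.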

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

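The tests of weaker ratios and of list members below the brightest, and the changes of list medians line by line, were chosen after the result was seen. All results here stand out because the HRZ2i effect differed between treatments by a test of the difference itself, within 1 limma fit or by the camera test on it. Slide and treatment cannot be told apart in any of them.

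From +Fe 7d to -Fe 7d the log2 ratio of HRZ2i over NT changed in 13 genes by that test. Of the uptake genes it changed by -5.60 for NAS1, -2.95 for DMAS1, -2.73 for TOM1 and -2.52 for IRT2. In the methionine cycle it changed by -2.46 for DEP and -1.23 for MTN, and for MIR by -2.15. Outside the lists the change was -3.69 for the antiporter Os12g0132500, -2.35 for the cytochrome P450 Os10g0440000, -2.77 for Os01g0871600, -2.76 for Os11g0262600, -1.21 for Os08g0414200 and 1.18 for the peroxidase Os01g0962900.

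The loss of the HRZ2i effect on uptake and methionine genes at -Fe 7d, with median differences of -2.75 and -1.13, was weighed against 2 technical explanations. Weaker ratios on the slide of -Fe 7d are argued against by 191 genes outside the 2 lists, called and at least 2-fold one way at +Fe 7d and -Fe 1d, whose median log2 ratio at -Fe 7d was 0.926 times that at +Fe 7d (1.67 and 1.81). Gene by gene, the quartiles of that ratio were 0.906 and 1.11. Loci of a shared probe sequence were each counted: 179 of the 191 stand for 119 distinct sequences, so the genes are not independent. Of these 179, 66 had an arm that was not well above background on any array of +Fe 7d, which limits their ratios. The 191 were not matched to the brightness of the list members, so weaker ratios among bright genes alone stay open. A signal ceiling at -Fe 7d is argued against for 10 members at least 4-fold below the brightest member, whose median log2 ratio there was -0.0589 after 1.81 at +Fe 7d. For the brighter members, saturation of the scanner is argued against by 0 saturated probes on the arrays of -Fe 7d. There 18 tested genes were also brighter in NT than the brightest member. A ceiling of another kind stays open for the brighter members, since the test could not decide. Of all genes as bright in NT as the median member (3.53% of those tested) 0 were higher in HRZ2i by 2-fold, but only 1 was at +Fe 7d too. A biological difference in the response to 7 days without iron, in which NT itself raised these lists, may account for the rest, and it cannot be told apart from the slide.

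Of the other lists at -Fe 7d minus +Fe 7d, iron translocation had a median difference of -0.47 and iron storage 0.61, and the camera calls of both held with an estimated correlation (adjusted p = 0.0182 and 0.0374). The following calls did not hold with an estimated correlation, whose adjusted p stands second. Iron regulators had a median of 0.01 but a mean of -0.71 and were called down (0.00847, 0.472). Photosynthesis genes had -0.33 (1.50e-06, 0.495), nitrogen transport and assimilation -0.10 (0.0129, 0.394), histones -0.04 (0.00341, 0.495) and phenylpropanoid genes -0.16 (0.0259, 0.396). Class III peroxidases had 0.05 (0.00152, 0.189), pathogenesis-related genes 0.06 (0.0380, 0.495) and germin-like genes 0.13 (0.0191, 0.495). The lines went both ways in 4 of these lists, with changes of the list median in lines 1 to 3 of -0.10, -0.14 and 0.09 for histones, -0.01, 0.15 and -0.04 for peroxidases, 0.09, 0.23 and -0.09 for pathogenesis-related genes, and 0.29, 0.03 and -0.59 for germin-like genes. Phenylpropanoid genes had -0.03, -0.19 and -0.34.

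At -Fe 1d minus +Fe 7d the methionine list had a median difference of -0.97 and held with an estimated correlation (camera adjusted p = 0.00981). The uptake list had -1.53 (3.25e-17, and adjusted p = 0.172 with an estimated correlation). In the same order peroxidases had 0.12 (0.0256, 0.443), germin-like genes 0.52 (0.000985, 0.443), expansins and extensins 0.10 (0.0243, 0.443) and histones -0.12 (0.00478, 0.658). The median of germin-like genes changed by 0.71, 0.35 and 0.03 in lines 1 to 3, so that line 3 showed almost none of it, and that of peroxidases by -0.0027, 0.12 and 0.03.

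At -Fe 7d minus -Fe 1d no call held with an estimated correlation, whose adjusted p again stands second. Uptake genes had a median difference of -1.02 (5.20e-16, 0.382), methionine genes -0.24 (0.00444, 0.397), translocation genes -0.27 (0.0137, 0.397) and regulators -0.25 (0.00923, 0.505). Expansins and extensins had -0.12 (0.0124, 0.505). Photosynthesis genes had -0.09 (0.0284, 0.938), metallothioneins -0.59 (0.0284, 0.636) and nitrogen genes -0.06 (0.0375, 0.505), and these 3 lists also missed the threshold with the line as replicate block (camera adjusted p = 0.0610, 0.230 and 0.0798). Line 1 carried most of the change in all 3, with -1.46 beside -0.14 and -0.23 in lines 2 and 3 for metallothioneins, -0.40 beside -0.15 and -0.12 for photosynthesis genes, and -0.41 beside 0.075 and -0.07 for nitrogen genes. Expansins and extensins had 0.03, 0.02 and -0.14 in lines 1 to 3.

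The number of splits was too small for a share under 0.05 in any comparison. Of the 4 sign patterns of 3 arrays, 1 gave as many genes as the real one, for 764, 607 and 690 genes at +Fe 7d, then -Fe 1d, then -Fe 7d, and the highest of the others was 0. Of the 10 splits of 6 arrays, 1 gave as many as the real 13 genes at -Fe 7d minus +Fe 7d, with 0 as the highest other, also among splits that part the arrays of each line. For the other differences the real value and the highest other were both 0, so that 10 of 10 splits gave as many.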

How the results depend on the processing

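The fit on lines 2 and 3 alone, which has no dye term, and the list test with the line as replicate block were chosen after seeing the data. No named gene call changed direction under the alternatives run. For lists the settings were compared by adjusted p alone, so a change of direction was not looked for. The balance of calls did turn from more higher to more lower genes with arrays as independent at all 3 treatments, in the replicate block at +Fe 7d and -Fe 7d, and with scale normalisation at +Fe 7d, and the other way for the NT response at -Fe 7d without NT 1 of +Fe 7d. The HRZ2i comparisons and differences held 109 named results, each a gene in 1 comparison, so a gene can count more than once. Of these 109, 108 kept their side of the threshold without background correction, 109 with all probes, 108 with scale normalisation, 101 with an offset of 16, 95 with median centring, 92 with the processed intensities, 91 without the dye term, 88 with the deposited ratios, 80 on lines 2 and 3 alone, 75 on the arrays of a comparison without the dye term and 63 with the trended robust fit. With all probes each gene was still read from the same probe, so that setting does not test whether its other probes go along. In the replicate block HRZ2 passed at +Fe 7d and -Fe 1d, histones, photosynthesis, metallothioneins and nitrogen genes lost the list calls already given, and 9 list calls were gained: regulators and jasmonate at +Fe 7d (camera adjusted p = 0.00411 and 0.0156), regulators and storage at -Fe 1d (0.0342 and 0.0458), and for -Fe 1d minus +Fe 7d translocation and storage (0.0339 each), photosynthesis (0.0141), pathogenesis-related (0.0395) and phenylpropanoid genes (0.0271). It changed no other call of a named gene or list in the HRZ2i comparisons, and kept 762 of 764, 606 of 607 and 682 of 690 calls over all genes. The arrays limit what can be seen: dim genes enter only with signal in 1 channel on 3 arrays, and the strict filter tests fewer genes. HRZ2i fits without a library leave 2 arrays in a treatment, whose spread is taken from the others. Without line 1 these 2 have the same dye orientation, so the dye term comes from the other treatments. At +Fe 7d and -Fe 1d they also share an NT replicate. NT fits without an extract of +Fe 7d or -Fe 1d leave 1 extract in that treatment, so their counts and p-values rest on the spread elsewhere. Where no cause is named, the cause was not tested.

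Counts are given as higher and lower genes at +Fe 7d, then -Fe 1d, then -Fe 7d, beside 434 and 330, 381 and 226, and 404 and 286. Without the dye term they were 261 and 143, 173 and 68, and at -Fe 7d 142 lower. With arrays as independent they were 1215 and 1317, 1680 and 1763, and 629 and 657. In the replicate block by line they were 1106 and 1175, 1235 and 1217, and 765 and 785. Scale normalisation gave 828 and 878, 648 and 439, and at -Fe 7d 518 lower. The strict filter gave 226 and 175, 123 and 95, and 195 and 155. The trended robust fit gave 151 and 30, 129 and 14, and 153 and 11. A 2-fold limit gave 235 and 84, 222 and 53, and 209 and 54. The arrays of a comparison alone, without the dye term, gave 245 and 110, 74 and 16, and 97 and 29. Lines 2 and 3 alone gave 182 lower at +Fe 7d, 212 and 64, and 268 and 100. At -Fe 1d the lower genes were 144 with the deposited ratios and 345 without a filter.

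For the difference of -Fe 7d minus +Fe 7d, beside 1 higher and 12 lower, arrays as independent gave 9 and 26, the replicate block 5 and 30, scale normalisation 3 and 23, the deposited ratios 2 and 2, an offset of 16 and median centring 0 and 4 each, the strict filter 0 and 3, the processed intensities 0 and 1, and the trended robust fit and lines 2 and 3 alone 0 and 0. The higher count was 0 without the dye term, and on the arrays of the comparison without it. All 13 genes were among those called with arrays as independent, in the replicate block and with scale normalisation. The deposited ratios moved the share of higher genes from 7.69% to 50%. For -Fe 1d minus +Fe 7d, beside 0 and 0, arrays as independent gave 30 and 48, the replicate block 12 and 16, and the deposited ratios 1 higher.

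Leaving out a replicate gave 100 to 307 higher and 26 to 197 lower genes at +Fe 7d, 90 to 275 and 17 to 151 at -Fe 1d, and 140 to 247 and 37 to 116 at -Fe 7d, each lowest without line 1. For -Fe 7d minus +Fe 7d it gave 0 to 0 higher and 0 to 1 lower, and for both other differences 0 to 0. The NT response at -Fe 7d had 9 to 31 higher and 3 to 61 lower genes, beside 263 and 343: 9 and 3 without NT 1 and 22 and 61 without NT 2 of +Fe 7d, and 11 and 17, 20 and 39, and 31 and 45 without NT 1, 2 and 3 of -Fe 7d. That at -Fe 1d, beside 5002 and 4164, had 651 and 596 without NT 1 and 3990 and 3135 without NT 2 of +Fe 7d, and 1569 and 1242, and 2916 and 2460 without NT 1 and 2 of -Fe 1d. Without an extract of +Fe 7d or -Fe 1d, 1 extract was left in that treatment. With the NT replicate number as replicate block, on NT 1 and 2 alone, the NT response at -Fe 7d had 31 and 45, being the same fit as without NT 3.

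Of 26 lists, 6, 5 and 4 were called at +Fe 7d, then -Fe 1d, then -Fe 7d, 12, 6 and 8 for -Fe 7d minus +Fe 7d, -Fe 1d minus +Fe 7d and -Fe 7d minus -Fe 1d, and 9 and 6 for the NT responses at -Fe 7d and -Fe 1d. With an estimated correlation the counts were in the same order 2, 0, 0, 4, 1, 0, 0 and 0. With fry they were 3 at -Fe 1d, 0 at -Fe 7d, then 4, 1, 0, 5 and 1. Ranks gave 4 for -Fe 7d minus +Fe 7d. The replicate block gave 11 for -Fe 1d minus +Fe 7d and 5 for -Fe 7d minus -Fe 1d. The correlation of the knockdown effect with the NT response went from 0.130 to 0.0560 and 0.116 with the 2 choices of disjoint extracts.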

Other observations

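The neighbour tests, the sets they ran on, the counting of a shared probe sequence once, and the dye test of the genes with a large ratio at all 3 treatments were chosen after the result was seen. In NT roots after 7 days without iron, defence and detoxification lists were lower. Pathogenesis-related genes fell in 4 of 101, 15 lower and 2 higher adjusted over the list alone, with Os07g0127700 at -2.25 ± 0.35 and the thaumatin Os11g0703100 at -1.97 ± 0.12 (camera adjusted p = 6.85e-05, but adjusted p = 0.335 with an estimated correlation). Glutathione S-transferases fell in 4 of 54, 7 lower and 1 higher adjusted over the list alone, with Os10g0530600 at -2.78 ± 0.31 (camera adjusted p = 4.22e-05, but adjusted p = 0.335 with an estimated correlation). Germin-like genes, none called by limma over all genes, had a median of -0.51, with 3 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00680, but adjusted p = 0.403 with an estimated correlation). After 1 day without iron, 2 laccases, which polymerise lignin, rose in NT, with Os03g0273200 at 6.96 ± 0.77 and Os01g0827300 at 4.08 ± 0.22. The phenylpropanoid list had 16 higher and 5 lower of 48 genes, 18 and 5 adjusted over the list alone (camera adjusted p = 0.0351, but adjusted p = 0.853 with an estimated correlation). Peroxidases had 13 higher and 33 lower, the same adjusted over the list alone, and glutathione S-transferases 4 and 17, or 4 and 18 adjusted over the list alone (camera adjusted p = 0.000119 and 0.0288, but adjusted p = 0.542 and 0.853 with an estimated correlation). Iron regulators had 5 lower of 8, 5 adjusted over the list alone (camera adjusted p = 0.0351, but adjusted p = 0.853 with an estimated correlation). With the NT replicate number as replicate block, which is the main NT fit without -Fe 7d NT 3, IDEF2 and IRO2 were not called (limma adjusted p = 0.0733 and 0.0778). None of the 5 was called without +Fe 7d NT 1 (limma adjusted p from 0.0696 to 0.238) or -Fe 1d NT 1 (0.0547 to 0.216), and without -Fe 1d NT 2 only bHLH060 was (the others 0.0532 to 0.101). Those day-1 samples differ from +Fe 7d in day and slide as well. Os07g0127700, Os11g0703100, Os10g0530600 and Os01g0827300 were named after their values were seen, and their calls were not refitted without each library.

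YSL2, an iron-nicotianamine transporter gene, was well above background in HRZ2i of lines 1 and 3 at each treatment, and in neither line 2 nor NT on any array. YSL2 is therefore 1 of the 78 genes, given below, that differed between lines 2 and 3 at every treatment. With NT at background no ratio is given, and limma did not call it at -Fe 7d (adjusted p = 0.268). Lowered together in HRZ2i at +Fe 7d and in iron-deficient NT were the cytochrome P450 Os07g0451300 (-2.07 and -2.89), the multicopper oxidase Os01g0127000 (-2.03 and -4.85) and the peroxidase Os01g0962900 (-1.18 and -1.79), put together after their values were seen. Both values rest on the same NT extracts of +Fe 7d, which alone can lower them together. The calls of Os01g0962900 at +Fe 7d and in NT, and of Os07g0451300 in NT, were not refitted without each library. Without line 1, Os01g0127000 was not called at +Fe 7d (limma adjusted p = 0.248), nor without line 3 (0.0567), and its NT call was lost without NT replicate 1 of +Fe 7d (0.0594).

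Genes with a large ratio at all 3 treatments numbered 179, called and at least 2-fold one way each time, or 119 distinct probe sequences. A hypothesis is that part of them mark a strain difference between the NT plants and the lines: 51 of the 119 had another such gene among the 5 tested genes on either side, where 1000 random draws gave a median of 6 and at most 19. The run from Os09g0353700 to Os09g0357400 held 6 of 9 tested genes, all lower in HRZ2i. Dye bias is argued against by 197 genes chosen on lines 2 and 3 alone, at least 2-fold one way on all their arrays: line 1, with dyes the other way round, had that sign in 98.5% of them. Of the 197, 161 belong to the set, and loci of a shared probe sequence were each counted among the 197. An effect of the knockdown that does not depend on iron stays open and was not tested, and genes 2-fold changed at +Fe 7d but under 0.5 in log2 size at -Fe 7d had 4 of 48 with such a neighbour, a number that 81 of 1000 draws reached.

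The lines also differed from each other. In 78 genes (66 distinct sequences) line 3 differed from line 2 at least 4-fold the same way at all 3 treatments, for instance the RNA-binding protein-like Os06g0170500 with mean log2 ratios of 7.71, 0.84 and 7.76 in lines 1 to 3. A genomic difference between the lines is a candidate explanation: 35 of the 66 had a neighbour of the set, where random draws gave a median of 2 and at most 10, and 33 lay on chromosome 11. Line 1 was within 2-fold of line 3 in 56 of them and of line 2 in 7.

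The slightly low ribosomal protein genes, with medians from -0.28 to -0.04 over the 9 arrays, were set against 2 technical explanations. A bias with brightness is argued against: 0 percent of 1000 random lists of matched brightness had a median as low as the list at any treatment, the lowest at +Fe 7d being -0.0303 beside -0.13. Dye bias is argued against by line 1, where the list median was below 0 on all 3 arrays. The camera calls were lost with an estimated correlation, and no biological explanation was tested.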
